A study of Bacillus subtilis with 3 samples.

How the data were processed

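Total RNA of *Bacillus subtilis* W168 was compared between daptomycin-treated and untreated parts of the same culture on 3 two-channel arrays, per the labels' protocols. The labels state 3 independent RNA preparations. Treated RNA carried Alexa Fluor 647 on arrays 1 and 2 and Alexa Fluor 555 on array 3. The files hold 1 table with a log2 ratio of the dye channels for each array, as deposited by the authors and called normalized in the labels. The scanner, the background correction, the normalization method and the averaging of duplicate spots are not given in the sources used here. Base 2 was taken from the values, many of which equal log2 of a ratio of small whole numbers. The medians over genes were -0.01, 0.12 and 0.00 on arrays 1, 2 and 3, so the values lie near 0 without further centring, and whether the authors centred them is unknown. Scanner intensities were not used here, so no value could be set against its background, and the number of arrays limits the precision. The table has 4116 rows, of which 10 are array controls that were left out of the tests. Each remaining row has its own gene name, so no probes were averaged.

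Gene names on the array follow an older nomenclature. Of 4106 names, 3036 matched symbols of the RefSeq table of assembly ASM904v1 directly and 57 more matched through older names set by hand from general knowledge of the nomenclature. That table was used for names and for which genes neighbour each other, and no coordinates are given because the build behind the array is not named. For the gene lists and named genes, 63 older names were replaced by current symbols.

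The plan set before the data were examined was to turn array 3 if its correlation across genes with the mean of arrays 1 and 2 was under -0.1, to take it as already turned if it was over 0.1, and to report no direction between these bounds. The plan did not name the coefficient. Pearson's r, which was used, was -0.04 and leaves the direction undecided under that plan. Spearman's rho was -0.20, under the lower bound, and would have asked for array 3 to be turned. Departing from the plan after the values were seen, array 3 was used as deposited and its direction called likely. The reason was the sign of the genes with the largest ratios on arrays 1 and 2, so their agreement on array 3 is not independent evidence. Read literally, the title and description of array 3 name untreated over daptomycin. Results with array 3 multiplied by -1 were computed as an added alternative.

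The log2 ratios of the 3 arrays were fitted with limma 3.58.1 (lmFit and eBayes, intercept fit, mean against 0) in R 4.3.3, for genes with a value on at least 2 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. Cultures are paired within an array. The tests of genes and lists are two-sided, and the permutation tests of distance between genes are one-sided. Gene lists were tested with camera at a preset correlation of 0.01, for 30 lists fixed before the data were examined, each with at least 3 measured genes, and counts of members past the threshold were also adjusted over the list alone. The list tests used genes with values on all 3 arrays. Ratios of small whole numbers were identified by a denominator of up to 8 and a numerator of up to 40 within a relative tolerance of 5e-05 of the linear ratio. After shifting the values, 0.24%, 0.32% and 0.19% of them on arrays 1, 2 and 3 met the same definition. Figures and further tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

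Named genes were chosen by a rule set before the data were examined. It took each measured LiaR regulon gene and, in each direction, the 12 largest means among genes past the threshold with the same sign on all 3 arrays. Where fewer than 5 genes passed in a direction, it took the 5 largest means of the same sign on all 3 arrays. For each list it took the 3 largest means past the threshold, or the 2 largest where none passed. Genes outside this rule are said to have been chosen after their values were seen.

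The procedure was tested on simulated data made by shuffling and randomly turning the signs of each array's values over 4094 genes, with 200 genes shifted by known amounts, in 20 simulations. Genes shifted by 1, 2, 4 and 7 on the log2 scale were called in 0%, 0.2%, 49.2% and 75.5% of cases, with 0 false calls per simulation. Shifting the LiaR list by 2 was recovered in 100% of the simulations, and 0 lists were called on average with no shift. These shuffled data hold no correlation between genes, so they say nothing of false calls that correlated genes would give. Each array was shuffled over all genes, so a simulated gene does not keep the spread of a real gene. The shares called are thus not detection rates for real genes of small spread.

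The alternatives set in advance were median-centring, scaling and quantile normalization of the arrays, a dye coefficient, a robust variance prior, no moderation, array weights, values on all 3 arrays only, rows matching the reference table only, a threshold of 0.01, a minimum log2 ratio of 1 in size and leaving out each array in turn. For lists they also included an estimated correlation, ranks and fry. Turning array 3 and leaving out ratios of small whole numbers were added after seeing the data. With 3 arrays, the sign of the ratios can be arranged in 4 ways, so a sign test of 1 gene cannot give a two-sided p below 0.25.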

Results

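The study measured how gene expression in *Bacillus subtilis* W168, a standard laboratory strain of this Gram-positive bacterium, changed after exposure to daptomycin, a calcium-dependent lipopeptide antibiotic that acts on the cell membrane. Wild-type cultures at an OD600 of 0.4 were divided into equal parts, 1 part received daptomycin at 1 µg/ml, and cells were collected 20 min later. RNA from the daptomycin part and the untreated part of a culture was labelled with different fluorescent dyes and hybridised to the same array. There were 3 arrays from 3 independent RNA preparations. Daptomycin RNA carried Alexa Fluor 647 on arrays 1 and 2 and Alexa Fluor 555 on array 3. Each array gave 1 log2 ratio per gene, for 4099, 4104 and 4103 genes on arrays 1, 2 and 3, and 10 further rows were array controls. The spread of the ratios differed between arrays, with an SD across genes of 0.68 on array 1, 1.84 on array 2 and 1.19 on array 3. Intensities were not used here, so the signal behind each ratio is unknown, and the number of arrays limits the precision.

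Ratios are given as daptomycin over untreated. This direction is taken from the labels for arrays 1 and 2. For array 3 the labels, read literally, name the ratio the other way round, and the deposited values point to daptomycin over untreated. Over all genes the values did not settle it, since the Pearson correlation across genes of array 3 with the mean of arrays 1 and 2 was -0.04, and Spearman's rho, -0.20, went against the direction used here. Ratios had the same sign on all 3 arrays for 807 genes as deposited and for 1122 with array 3 turned. However, 9 genes had ratios of at least 4 in size on both arrays 1 and 2. All 9 were positive there and on array 3 as deposited, where the lowest was 4.73. These are not 9 independent signs, since 6 belong to the *lia* operon and all 9 lie within 1 stretch of 176 file rows. A signal that follows position on the array stays open. On these 9 genes alone, daptomycin over untreated is called the likely direction of array 3 and was used below. List calls and signs of named genes that change with array 3 turned are given with the main values.

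The first question was which genes responded to daptomycin. The *lia* operon genes *liaI*, *liaH* and *liaG* had the 3 highest mean ratios, and the other 3 genes of the operon lay below *yvpB* and *yvrI*, given further on. This operon encodes the LiaS sensor kinase, the LiaR response regulator and the inhibitor LiaF of a cell envelope stress system, with LiaI, LiaG and the phage shock family protein LiaH. The log2 ratio of *liaI* was 11.83 ± 3.17 (SD, n = 3) and that of *liaH* was 10.68 ± 4.13 (SD, n = 3). The other operon members had lower ratios, 7.88 ± 1.65 for *liaG*, 7.11 ± 0.39 for *liaF*, 6.79 ± 0.26 for *liaS* and 5.73 ± 1.42 for *liaR* (SD, n = 3 each). All 6 genes were positive on all 3 arrays. On array 2, *liaI* and *liaH* had nearly the same ratio, 15.44 each, differing by 0.0001, and the size of these ratios is uncalibrated. Of the 9 measured LiaR regulon genes, these 6 passed when adjusted over the list alone, and 0 passed when adjusted over all 4106 genes. The smallest adjusted p from limma over all genes was 0.0881, for *liaS* and *liaF*, and it was 0.956 for *liaI*, *liaH*, *liaG* and *liaR*. The direction of array 3 was judged on 9 genes that include these 6, so their SDs and p-values rest on that choice. The smallest limma adjusted p over all genes was 0.756 with array 3 turned and 0.897 without array 3. The regulon genes outside the operon, *yhcY* at 0.67 ± 0.89, *yhcZ* at 0.83 ± 0.61 and *azr* at 2.00 ± 2.42 (SD, n = 3 each), did not pass either adjustment. The mean of *azr* rests on array 2, at 4.78, and was 0.61 without it. With array 3 turned, the mean ratios of *liaI* and *liaS* were 4.81 and 2.34, still positive. The order of the genes then changed, with *liaH* at 5.11 above *liaI*, and *yvrI* at 4.02 and *yvpB* at 3.68 above *liaG* at 3.45.

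**Figure D1:**
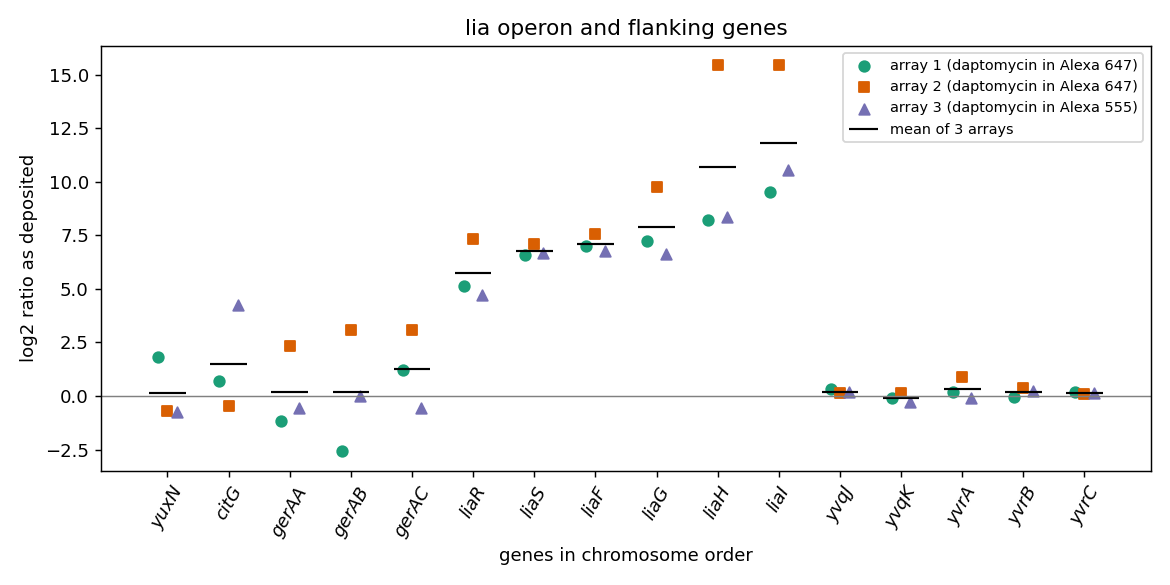
Log2 ratio of daptomycin over untreated (vertical axis) for the 6 *lia* operon genes and 5 measured genes on either side in chromosome order (horizontal axis). Each symbol is 1 array and each bar the mean of 3 arrays; the operon genes lie between 4.73 and 15.44 on every array, and the highest value of the flanking genes is 4.25, for *citG* on array 3.

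No gene passed the adjusted threshold of 0.05 over all 4106 genes tested with limma. At an unadjusted limma p under 0.05 there were 59 genes, 47 higher and 12 lower, and an ordinary one-sample statistic without moderation also called 0 genes. The 59 genes are below the share of 0.05 that no change at all would give. With the signs of the arrays arranged otherwise there were 97, 108 and 27 such genes. The count became 7 with quantile normalization across arrays, all higher, namely *liaI*, *liaH*, *liaG*, *liaF*, *liaS*, *liaR* and *yvpB*. It became 2, *liaS* and *liaF*, with array weights. The 5 genes with the largest positive means of the same sign on all 3 arrays were *liaI*, *liaH*, *liaG*, *yvpB* and *yvrI*. This holds for array 3 as deposited, and with it turned all 5 have opposite signs on arrays 1 and 3. The log2 ratio of *yvpB* was 7.52 ± 2.37 and that of *yvrI*, which encodes a sigma factor, was 7.25 ± 3.10 (SD, n = 3 each). Both lie in the same stretch of 176 file rows as the *lia* operon, and so do all 15 genes with ratios of at least 3 in size and of the same sign on arrays 1 and 3. This stretch was set after the values were seen, by the first and last rows of 12 genes given further on. Of those 12 genes, 5 are among the 15 and lie in the stretch by construction. The 5 lowest means of one sign were small beside these. They were -1.95 ± 2.28 for the spore coat gene *cotC*, -1.89 ± 1.46 for *ywjC*, -1.83 ± 1.21 for *yhcQ*, -1.71 ± 1.16 for *mrpF*, part of a sodium and proton antiporter, and -1.69 ± 1.70 for *ybaN* (SD, n = 3 each). The values of *yhcQ* and *mrpF* were ratios of small whole numbers on all 3 arrays, and those of *ybaN* on 2. The mean of *cotC* rests on array 3, at -4.585 and also such a ratio, against -0.72 and -0.54 on arrays 1 and 2. None of these 10 genes passed in the main test, and the means of *cotC*, *ywjC*, *mrpF* and *ybaN* turn positive with array 3 turned.

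The next question was whether groups of genes with a shared function or regulator moved together. Of 30 gene lists fixed before the data were examined, 10 passed camera with a preset inter-gene correlation of 0.01, 4 of them higher and 6 lower than the remaining genes. None of the 10 passed with an estimated correlation (lowest adjusted p = 0.688), and none passed fry, which tests each list on its own (lowest adjusted p = 0.263). Over the 10 lists the estimated correlation ranged from 0.04 for SigM to 0.95 for the LiaR regulon. It was 0.86 for ribosomal proteins, 0.82 for heat shock and 0.71 for glycolysis. Where it lies far above 0.01, the preset counts correlated genes as nearly independent, and the camera p-values below can be far too small. Camera compares each list with the other genes, whose mean log2 ratio was about 0.21, while the median over all genes of the mean ratio was 0.05 and the mean over genes was 0.82 on array 2. The LiaR regulon and the SigD list kept their call and direction when any 1 array was left out, and the other 8 lists did not. The difference of the SigD mean from the other genes was nevertheless small without array 2, at -0.07, against -0.56 and -0.63 without arrays 1 and 3.

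Among the lists above the other genes, the LiaR regulon had a median log2 ratio of 6.79 over its 9 members (camera adjusted p = 3.92e-17). Leaving out array 3, on which the direction was judged, gave an adjusted p of 5.59e-11, and turning array 3 gave 0.228. The SigM regulon, controlled by an extracytoplasmic sigma factor that responds to cell wall stress, had a median of 0.28 over 33 genes, and 13 of them were positive on all 3 arrays (camera adjusted p = 0.000684). Its member *amj*, a lipid II flippase gene, had a ratio of 3.18 ± 2.24, and *ypuA* had 1.86 ± 1.38 (SD, n = 3 each), and neither passed. The mean of *ypuA* was -0.25 with array 3 turned, and its values were ratios of small whole numbers on all 3 arrays. The SigW regulon, which holds genes against membrane-active compounds, had a median of 0.15 over 51 genes, and 14 were positive on all 3 arrays (camera adjusted p = 0.0345). Its mean, 0.23, was close to the mean of the other genes, 0.21, and its members with the largest means were *yoaG* at 2.24 ± 2.46 and *ydjI* at -1.51 ± 1.81 (SD, n = 3 each), neither passing. Without array 2 their means were 0.83 and -0.53. Pyrimidine synthesis had a median of 0.25 over 10 genes (camera adjusted p = 0.0425), with *pyrAA*, a carbamoyl phosphate synthase gene, at 0.75 ± 0.45 and the dihydroorotase gene *pyrC* at 0.55 ± 0.31 (SD, n = 3 each), neither passing. Over their lists alone, 0 members of SigM, SigW or pyrimidine synthesis passed. With array 3 turned the SigM and SigW calls ended and their differences changed sign. The pyrimidine call ended too (camera adjusted p = 0.309), with a difference of -0.17 from the other genes and its test statistic on the higher side. Without array 3 the SigM and SigW calls ended (adjusted p = 0.348 and 0.426), and without array 1 the SigW call ended (adjusted p = 0.991). The SigW and pyrimidine calls also ended with median-centred arrays (adjusted p = 0.0568 for both) and on ranks (adjusted p = 0.0513 for both). The pyrimidine call ended without any of the arrays, with adjusted p of 0.22, 0.0805 and 0.155 without arrays 1, 2 and 3.

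Among the lists below the other genes, the SigD regulon and flagellar operon, genes of motility, had a median of -0.24 over 39 genes, and 21 of them were negative on all 3 arrays (camera adjusted p = 5.19e-08). The chemoreceptor gene *mcpB* had a ratio of -0.63 ± 0.19 and the chemoreceptor gene *tlpA* had 0.92 ± 2.73 (SD, n = 3 each), and neither passed. The mean of *tlpA* rests on array 2, at 4.04, and was -0.64 without it. The ribosomal protein list had a median of -0.21 over 53 genes (camera adjusted p = 3.07e-06), with medians of -0.13, -0.70 and 0.23 on arrays 1, 2 and 3, and *rpsR* at -0.49 ± 0.49 and *rpsP* at -0.42 ± 0.52 (SD, n = 3 each) did not pass. Glycolysis and pyruvate dehydrogenase had a median of -0.16 over 17 genes (camera adjusted p = 0.0121), with the glucose transporter gene *ptsG* at -0.33 ± 0.54 and the triose phosphate isomerase gene *tpiA* at -0.32 ± 0.31. The CtsR and HrcA heat shock list had a median of -0.19 over 12 genes (camera adjusted p = 0.013), with the chaperone gene *dnaK* at -0.28 ± 0.34 and *mcsA* at -0.27 ± 0.29. Purine synthesis had a median of -0.20 over 16 genes, 9 of them negative on all 3 arrays (camera adjusted p = 0.013), with *xpt* at 1.62 ± 1.83 and *purL* at -0.42 ± 0.29. The PhoP phosphate regulon had a median of -0.22 over 20 genes (camera adjusted p = 0.0345), with the phosphate-binding protein gene *pstS* at -1.65 ± 2.25 and *ydhF* at -1.66 ± 0.89. Errors are SD with n = 3, and no gene named for these 6 lists passed over all genes or over its list alone. The values of *xpt* and *ydhF* were ratios of small whole numbers on all 3 arrays. The mean of *pstS* rests on array 3, at -4.25, against -0.34 and -0.38 on arrays 1 and 2. With array 3 turned the means of *xpt*, *pstS* and *ptsG* changed sign, to -0.69, 1.18 and 0.08.

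Array 2 decided several of these lists. Without array 2 the ribosomal protein, glycolysis and heat shock lists were no longer called and lay above the other genes instead (adjusted p = 0.295, 0.377 and 0.819), and the purine call ended (adjusted p = 0.819), with its mean 0.18 above that of the other genes and its test statistic on the lower side. Their median ratio on array 2 was -0.70, -0.64, -0.60 and -0.31, against -0.13, 0.01, -0.03 and -0.13 on array 1. The PhoP list had medians of -0.25, 0.45 and -1.07 on arrays 1, 2 and 3, and its call ended without array 1 (adjusted p = 0.1), without array 3 (adjusted p = 0.771) and with array 3 turned, where its difference changed sign (adjusted p = 0.14). The SigD, ribosomal protein, purine, glycolysis and heat shock lists were called lower with array 3 turned as well. With a dye coefficient in the model, the ribosomal protein, purine, glycolysis, heat shock and pyrimidine calls ended (adjusted p = 0.143, 0.292, 0.291, 0.27 and 0.144), and the LiaR, SigM, SigW, SigD and PhoP calls were kept. That fit cannot separate dye from other differences of array 3, the only array with swapped dyes. The heat shock and glycolysis calls also ended with scaled arrays (adjusted p = 0.116 and 0.137) and with array weights (adjusted p = 0.607 and 0.864). Array weights ended the purine call (adjusted p = 0.176), and ranks ended the PhoP call (adjusted p = 0.0588).

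**Figure D2:**
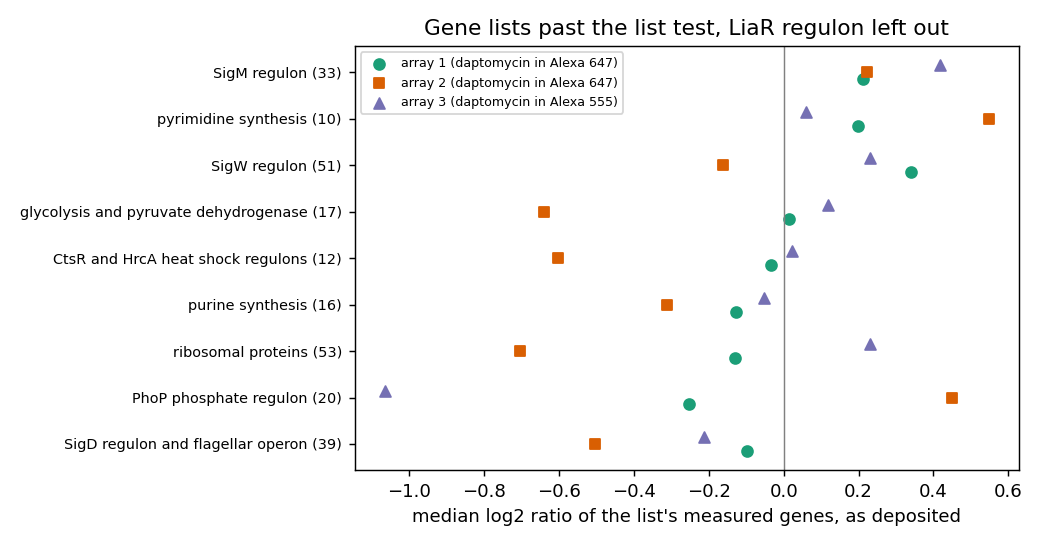
Median log2 ratio of daptomycin over untreated (horizontal axis) on each of the 3 arrays for 9 gene lists past the camera test, with the number of measured genes in brackets; the LiaR regulon is left out because its median, 6.79, lies far outside the range. Each symbol is 1 array; the SigD list is negative on all 3 arrays, whereas the ribosomal protein list is at -0.70 on array 2 and 0.23 on array 3.

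The other 20 lists did not pass camera, with adjusted p from 0.0601 to 0.908, although 11 of them were called in at least 1 alternative. Lists for other targets of membrane or wall damage were among them. The Bce, Psd and Yxd peptide detoxification transporters had a median of 0.24 over 7 genes, with *bceA* at 1.85 ± 3.23, and 0 of the 7 genes were positive on all 3 arrays. Both values rest on array 2, where *bceA* was at 5.57, and without it the mean of *bceA* was -0.01 and the list median -0.08. Phospholipid and glycolipid synthesis had a median of 0.10 over 15 genes, with *plsC*, an acyltransferase gene of phospholipid synthesis, at -0.74 ± 1.24 and *plsX*, an early gene of the pathway, at 0.59 ± 0.26. The mean of *plsC* rests on array 3, at -2.17, against 0 and -0.06 on arrays 1 and 2, and was 0.70 with array 3 turned. Fatty acid synthesis and desaturation had a median of 0.43 over 14 genes, with the desaturase gene *des* at 0.91 ± 0.79. This list was called higher without array 2 (camera adjusted p = 0.00145), with scaled arrays (0.029), with a dye coefficient (0.0298), with array weights (0.00376) and without ratios of small whole numbers (0.0356). Peptidoglycan synthesis and elongation had a median of 0.05 over 21 genes, with the shape gene *mreBH* at 0.64 ± 0.34, or -0.03 with array 3 turned. The CssR secretion stress list had a median of 0.26 over 4 genes, with *cssR* at 0.77 ± 0.84, and was called higher with array weights (camera adjusted p = 0.0338). The WalR cell wall regulon had a median of -0.10 over 10 genes, with *pdaC* at 2.88 ± 2.05 (SD, n = 3 for each gene). The values of *pdaC* were ratios of small whole numbers on 2 arrays, and its mean was 0.16 with array 3 turned. The SigB general stress regulon, with 48 genes, had a median of -0.05, and was called lower without array 3 (camera adjusted p = 0.0355) and without ratios of small whole numbers (0.0433). Markers of cells in another state did not pass either, with a median of -0.38 over 14 spore formation genes and 0.42 over 17 competence genes. The spore formation list was called lower with a dye coefficient (camera adjusted p = 0.0197). The competence list was called higher without array 3 (camera adjusted p = 0.0355) and with array 3 turned (0.0101), and its positive median rests on array 2, being -0.24 without it. With array 3 turned, the ATP synthase, PerR, Spx and citrate cycle lists were called lower (camera adjusted p = 0.00568, 0.00958, 0.0446 and 0.00284) and the Fur list higher (0.0121). Of 74 genes named by the rule, 43 had a mean that moved by over 1.5 times or changed sign without array 2.

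A further comparison asked how far the arrays agreed and whether the dye mattered. Correlations are across 4094 genes, which are not independent replicates. Pearson's r was 0.12 between arrays 1 and 2, 0.26 between arrays 1 and 3 and -0.14 between arrays 2 and 3, and Spearman's rho was 0.04, 0.04 and -0.23. Over the 2628 genes with no ratio of small whole numbers on any array, r was 0.32, 0.61 and 0.11, and rho was 0.12, 0.03 and -0.14. Ratios had the same sign on all 3 arrays for 807 genes, 19.7% of those compared, where chance gives 25%. There were 1122 such genes, 27.4%, when array 3 was turned. There were 26 genes at 1 or above on all 3 arrays and 2 genes at -1 or below. In a fit with a dye coefficient, 0 genes passed for dye with limma. Only array 3 has swapped dyes, so this coefficient cannot be told apart from any other difference of array 3 from arrays 1 and 2. At an unadjusted p under 0.05 there were 159 genes, of which 140 were higher in Alexa Fluor 647. Turning array 3 exchanges the dye and daptomycin coefficients, and the dye count is then 126 genes, 39 of them higher in Alexa Fluor 647. Both counts are below the share of 0.05 of the 4094 genes that no dye effect would give. Many ratios were log2 of a ratio of small whole numbers, making up 13.4%, 26.3% and 18.7% of the values on arrays 1, 2 and 3. The median of these values minus the median of the others was 0.02 on array 1, 2.53 on array 2 and -1.03 on array 3.

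**Figure D3:**
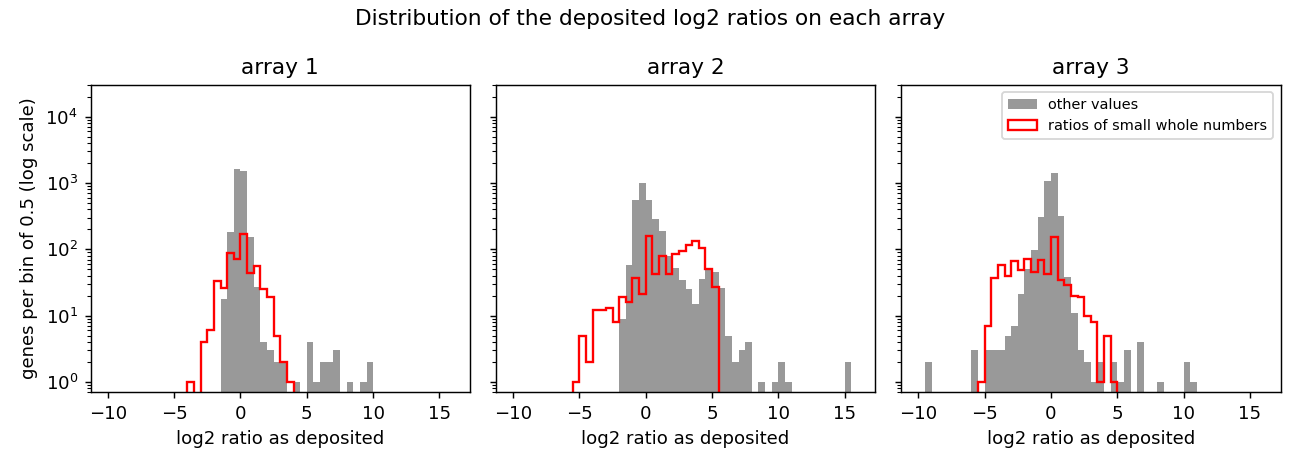
Number of genes (vertical axis, log scale) in bins of 0.5 of the log2 ratio of daptomycin over untreated (horizontal axis) on arrays 1, 2 and 3. The filled histogram holds most values and the red line the ratios of small whole numbers, whose median is 0 on array 1, 2.46 on array 2 and -1 on array 3.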

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

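Turning array 3 and leaving out ratios of small whole numbers were chosen after seeing the data, and the other alternatives were set before. The count of genes called by limma was 0 in the main setting and became 7 with quantile normalization, 2 with array weights and 2 without ratios of small whole numbers; it was 0 in the remaining settings, 0 to 0 without each array included. At a threshold of 0.01 or with a minimum ratio of 1 it also stayed at 0. The count of gene lists called was 10 in the main setting (4 higher, 6 lower) and 0 with an estimated correlation and 0 with fry; it was 7 to 11 without each array and 11 with array 3 turned. Centring gave 8 lists (2 higher, 6 lower) and scaling gave 9 (5 higher, 4 lower). Of the 10 lists, 5 kept their call and direction with array 3 turned and 5 without array 2. Among lists called in the main setting or without array 2, the direction of the camera test changed without array 2 for 4, whose mean minus the other genes' mean became 0.12 for heat shock, 0.14 for ribosomal proteins, 0.15 for glycolysis and 0.75 for the citrate cycle, which was called there. Across the fits without 1 array, their lowest differences, all without array 3, were -0.73, -0.89, -0.72 and -0.55. The citrate cycle difference was 0.07 in the main setting, where the test pointed lower, and -0.80 with array 3 turned, where it was called lower. The purine, ATP synthase and PerR differences also turned positive without array 2, at 0.18, 0.15 and 0.10, with no call. With array 3 turned the direction of the test changed for 4 lists called in either setting, with differences of -0.36 for SigM, -0.26 for SigW, 0.50 for PhoP and 0.19 for the Fur regulon, which was called there. Apart from the construction of these alternatives, the cause was not tested. Of 74 named genes, 18 changed sign with array 3 turned, 8 without array 2, 2 without array 3 and 0 without array 1; none of the 6 *lia* operon genes did. Each probe on its own was not run, because each gene name has 1 row. No paired analysis was possible because there is 1 group and the culture is already paired within the array. Signal over background, which would limit small ratios, was not analysed here.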

Other observations

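The genes in this paragraph and the next were chosen after their values were seen, and none passed over all genes. Their means and signs are for array 3 as deposited, and with it turned a gene positive on all 3 arrays has opposite signs on arrays 1 and 3. The tryptophan synthesis genes *trpE*, *trpD*, *trpC* and *trpB* had log2 ratios of 0.86 ± 0.74, 0.78 ± 0.35, 0.58 ± 0.25 and 0.56 ± 0.31, positive on all 3 arrays, while *trpF* was at 0.27 ± 0.60 and *trpA* at -0.48 ± 1.97 (SD, n = 3 each), both negative on array 2. These genes were not tested as a group. The value of *trpA* on array 2 was a ratio of small whole numbers. Of the genes of the SigO locus, *yvrI* and *yvrL* were positive on all 3 arrays, with *yvrL* at 2.88 ± 1.01, while *oxdC*, a known SigO target, was at 0.34, 0.27 and -4.09 on arrays 1, 2 and 3. The *oxdC* value on array 3 was a ratio of small whole numbers, a kind of value that was low on that array over all genes. The DNA repair gene *radC*, a SigM list member, was at 1.51 ± 0.46.

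Some lists had many genes with the same sign on arrays 1 and 3, where 22.3% of all genes were positive on both and 25.1% negative on both. The fatty acid list had 10 of 14 genes positive on both arrays 1 and 3. Among these 10 was *fabHB* at 1.51 and 2.44, both ratios of small whole numbers, against -0.08 on array 2. Of these 10 genes, 5 were positive on array 2 too. In the SigW regulon 32 of 51 genes were positive on both, 14 of them on all 3 arrays. In the spore formation list 9 of 14 genes were negative on both, and in the PhoP list 14 of 20 were. Only 3 of these 14 and 6 of these 20 genes had no ratio of small whole numbers on any array. Over all genes such ratios had a median of -1 on array 3, and this was not separated from a list effect. The phosphate-starvation gene *glpQ* was at -1.74 and -2.02 on arrays 1 and 3 and at -0.59 on array 2. Its value on array 1 was a ratio of small whole numbers. The counts of genes with the same sign hold for array 3 as deposited, and with it turned the same genes have opposite signs on arrays 1 and 3. Neither a difference between arrays nor an excess over all genes was tested.

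The tests on array 3, on the 12 genes that split the arrays and on ratios of small whole numbers were chosen after the results were seen, and those on adjacent genes and on sign patterns before. A candidate explanation for the *lia* operon being positive in all 3 deposited columns is that array 3 was left unturned and that these probes prefer Alexa Fluor 647. Of the 9 genes with ratios of at least 4 in size on arrays 1 and 2, 6 belong to the 6-gene operon, which a preference of single probes that ignores operons would not give. All 9 genes lie within the same 176 rows of the table, whose order need not follow position on the array. A signal that follows position on the array stays open, as does an error in the dye labels of array 3.

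A set of 12 genes, taken after viewing the values with a minimum of 4 on arrays 1 and 3 or of 6.5 on array 2 and under 2 elsewhere, split array 2 from the other arrays. Log2 ratios of *yvcQ*, *yvdQ*, *yvkB*, *yvnB* and *yvoD* were 5.33 to 10.28 on arrays 1 and 3 and -0.11 to 1.08 on array 2, whereas *yvcA*, *yvpA*, *yvrH*, *yvyH*, *yvzB*, *ywdD* and *ywfA* were 6.83 to 10.23 on array 2. Transcription spreading from the *lia* operon would raise its flanking genes, and the median of 10 of them was at most 0.19 on arrays 1 and 3. The 5 genes on the *liaI* side lay between -0.29 and 0.32 there. On the *liaR* side, *gerAC*, *gerAB*, *gerAA* and *citG* ranged from -2.585 to 4.25 on arrays 1 and 3. Their values were ratios of small whole numbers on all 3 arrays, so the pooled median cannot decide on spreading. A dye preference of these spots that is the same on every array would give like values on arrays 1 and 2, which carry the same dyes. These arrays differed by at least 4.86 for each of the first 5 genes, above 2 SD of that difference over all genes, 3.75. However, the 5 genes were picked at 4 or more on array 1 and under 2 on array 2. A gap was thus set by the choice, so this comparison cannot decide, and a dye effect specific to an array stays open too. The 12 genes lie nearer to the *lia* rows than random genes in file order (permutation p = 1e-05, the smallest that 100000 permutations can give). They also do in chromosome order (permutation p = 3e-05), so the orders cannot be told apart. Spot positions were not used here, and file order need not follow them, so a spot-related signal was not tested and stays open. For array 2 closeness in file order depends on the minimum chosen, since at a minimum of 4 there were 348 genes (permutation p = 0.064 for distance to the *lia* rows). Of these, 13 lie within the 176 rows. At a minimum of 5 there were 108 genes, 8 of them in these rows (permutation p = 0.46). At a minimum of 6 there were 12 genes, 7 of them in these rows (permutation p = 1e-05). The 5 genes of arrays 1 and 3 were taken at a minimum of 4 (permutation p = 1e-05). The 176 rows run from the first to the last of the 12 genes, so all 12 lie there by construction.

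Ratios of small whole numbers were high on array 2 and low on array 3. A response of weakly expressed genes to daptomycin would shift them the same way on both arrays, and their median minus that of the other values was 2.53 on array 2 and -1.03 on array 3. An excess of Alexa Fluor 647 at faint spots is a candidate explanation, since the 7 *Escherichia coli* control rows, which hold no transcript of the studied bacterium, had a median of 2.70 on array 2 and -0.59 on array 3. This reading also takes array 3 as daptomycin over untreated. Array 1 has the same dyes as array 2, and its controls had a median of 0.05, so any such excess would be specific to an array.

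Adjacent genes on the chromosome were tested for responding together, with the *lia* operon left out. The Spearman correlation between adjacent genes of the mean of arrays 1 and 3 was 0.18, above the 1000 shuffled orders, whose highest was 0.12. The value of a gene on array 1 with its neighbour on array 3 gave -0.01, within the shuffled range of -0.07 to 0.06, a comparison added after the first was seen. However, a gene's own values on arrays 1 and 3 had a rho of 0.03 over 2628 genes with no ratio of small whole numbers. A value near 0 between neighbours across arrays was thus likely from the start and cannot decide. Within single arrays the correlation between adjacent genes was 0.19, 0.49 and 0.21 on arrays 1, 2 and 3, each above its shuffled orders. A shared response and an effect of each array cannot be told apart.

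The 4 sign patterns of the 3 arrays are too few for a share under 0.05. The real pattern gave 0 called genes and the highest of the others gave 0, so 4 of the 4 patterns gave as many. For lists the real pattern gave 10 and the highest of the others 13, and 3 of the 4 patterns gave as many.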
